A study of Mus musculus with 36 samples.

How the data were processed

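Total RNA from mouse lung was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read out most annotated genes with several probes each. Per the labels, mice of the strains A/J and C3H were left untreated or received NNK, the tobacco-specific nitrosamine 4-(methylnitrosamino)-1-(3-pyridyl)-1-butanone, at 100 mg/kg once a week for 4 weeks, and lungs were taken before mature tumours formed. Untreated lungs were taken at weeks 0, 3, 6, 9 and 12 and NNK-treated lungs at weeks 3, 6, 9 and 12 after exposure. Each of the 18 groups of strain, treatment and week had 2 arrays, 36 in all. The labels do not say whether the 2 arrays of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

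The deposited values are intensities on a linear scale, 1 per probe set and array, made by the authors with PLIER in Affymetrix Expression Console per the submitters' processing notes. The versions, the background and normalization settings and the genome build were not given in the sources used here, so no coordinates are printed. The median deposited intensity of an array lay between 285 and 347 and the highest between 22074 and 62888. An array's intensities give no read depth, and the number of arrays limits the precision.

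Values were turned to log2(intensity + 16), so changes of dim genes are understated. The array medians on this scale spanned 0.268, more than the 0.1 allowed beforehand, and the arrays were quantile-normalized to each other. Of 35556 probe sets, 21789 had 1 gene symbol in the probe table, 1621 had several and 12146 were not named there. The Entrez gene IDs of 21698 of the named probe sets were found in a gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. For each of 19938 genes the probe set with the highest mean was kept, and the 14953 genes at or above the 25th percentile of mean level were tested. Probe sets with no or several symbols were left out of the comparisons and tested separately for the closing section. Cdkn1a and H2-K1 lie on probe sets of several symbols, and Bax was not in the probe table, so these genes were not analysed here.

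All comparisons came from 1 limma fit with a mean for each of the 18 groups and 18 residual degrees of freedom, with moderated variances and Benjamini-Hochberg adjustment at 0.05. The NNK change of a strain was the mean of its 4 weekly differences between NNK-treated and untreated arrays. The strain difference was the mean over 5 weeks of A/J minus C3H in untreated arrays. The week trend was a linear contrast over weeks 0 to 12 in untreated arrays, printed as log2 change over 12 weeks. Levels are means of log2 values with the SD over arrays, and changes carry the standard error of the fit. Every p printed for a gene or a list in these comparisons is an adjusted p.

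Of 44 gene lists of cell types and pathways, written from general knowledge, 42 with at least 5 measured genes were tested with camera at its preset correlation of 0.01, and beside it with a correlation estimated for each list, which allows for genes that vary together. The thyroid list had 4 measured genes and the list of sex-linked genes 2, and these were not tested. The fry test was run as well. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. The list test of the difference between the strains' week trends was added after the data had been seen.

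Genes were named by a rule. It took the 10 largest rises and 10 largest falls past the threshold with the same direction in every week, where the comparison had weekly values. It took up to 4 members with the smallest p from each described list, and 3 rises and 3 falls for each weekly contrast. Lists were described where camera called them, and 9 lists on DNA damage, proliferation, lung cells, immune cells and xenobiotic responses were described for NNK in any case. The results of 2 of the tested lists are not reported here. A few other members of the p53 list, the skin genes Krt10 and Ivl, and genes that mark doubtful arrays were named after their values had been seen. The scale, filters, comparisons, lists, naming rule and the alternatives listed first in the next paragraph were chosen before the data were examined.

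The alternatives chosen then were the deposited scale without normalization, a pseudocount of 1, no filter on dim genes, a filter at the 50th percentile, trended robust variances, array weights, the array number as a block, each strain's own arrays, an additive model of treatment and week, and each array left out in turn. Chosen after seeing the data were the array median as a covariate, 1 variance per strain, leaving out week 6 with 1 untreated A/J array of week 0, and using weeks 6 to 12 only. Lists of cornified skin genes and of clock genes of opposite phase were also added then.

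The scripts were tested on simulated arrays in which 200 of 14953 genes were changed, 100 by 0.5 and 100 by 1 on the log2 scale. For NNK in A/J, 97% and 100% of the changed genes were recovered, with 40 unchanged genes called. For NNK in C3H, 99% and 100% were recovered, with 1 unchanged gene called. For the difference between the strains' NNK changes, 92% and 99% were recovered, with 13 unchanged genes called. For the strain difference 98% and 100% were recovered with 15 unchanged genes called, and for the week trend 94% and 100% with 22. Single weeks had 2 arrays against 2. For A/J at week 6, 83% and 98% were recovered, with 36 unchanged genes called. For C3H at week 3, 78% and 98% were recovered, with 4 unchanged genes called. Unchanged genes were a larger share of the calls than the threshold of 0.05 allows, except for NNK in C3H and C3H week 3. Each comparison was simulated in a single draw. The small excess for the strain difference and for the difference between the strains' NNK changes may therefore be chance. The excess was largest for NNK in A/J and A/J week 6, so the A/J counts may hold more unchanged genes than the threshold implies. A simulated list of 20 genes shifted by 0.2 had p = 2.47e-33 at the preset correlation and p = 3.16e-09 with an estimated correlation, and 0 of 41 other lists passed. The simulated genes were drawn independently of each other. This simulation therefore cannot show how the preset correlation performs for lists whose genes vary together. Software was R 4.3.3 with limma 3.58.1, data.table version 1.17.8 and statmod 1.5.0, and Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9.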

Results

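NNK is a tobacco carcinogen that is activated to DNA-alkylating products in the lung. A/J mice are susceptible to lung tumours after NNK and C3H mice are more resistant. The comparisons asked which genes NNK changed in each strain, whether these changes differed between the strains, and how untreated lungs of both strains differed and moved over the weeks. Changes are on the log2 scale, and levels are means of normalized log2 values over arrays.

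In A/J lungs, NNK raised genes of the p53 DNA damage response, ciliated cells, cholesterol synthesis, alveolar type 2 cells and the interferon response. Of these lists the p53 list held its call with an estimated correlation, and the others did not (adjusted p = 0.286, 0.243, 0.286 and 0.305 with an estimated correlation, in that order). The largest rise was that of Retnla, which encodes a resistin-like molecule secreted by airway cells and alternatively activated macrophages. Of 23 endothelial genes 6 fell, and this list's call was also lost (adjusted p = 0.305 with an estimated correlation). Over weeks 3 to 12, 1502 of 14953 genes changed, 1113 upward and 389 downward, and 1209 of them moved the same way in all 4 weeks. The median size of these changes was 0.20, and 28 genes changed by at least 1.5-fold. The simulation called 40 unchanged genes in this comparison, more than the threshold of 0.05 allows, so the 1502 may hold an excess of unchanged genes. On the 18 A/J arrays alone, with 9 residual degrees of freedom, 483 genes passed, with 1 variance per strain 735, and without week 6 and 1 untreated week 0 array 492 passed.

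Retnla (probe set 10436095) rose by 1.83 ± 0.18 (SE) in A/J, from 10.11 ± 0.42 to 11.94 ± 0.37 (SD, n = 8 arrays each, adjusted p = 1.33e-06). Ltf (10589703), which encodes the iron-binding secretory protein lactoferrin, rose by 1.36 ± 0.17, from 8.87 ± 0.40 to 10.23 ± 0.46 (adjusted p = 1.86e-05). Clca3b, of a family of secreted chloride channel regulators, rose by 1.23 (adjusted p = 0.000114). Mfsd2a, a lysophospholipid transporter, rose by 0.95, and Lrg1, an acute-phase glycoprotein, by 0.90. A2ml1, a protease inhibitor, rose by 0.90, Plcd4, a phospholipase, by 0.84, and Ccl8, a chemokine, by 0.83. Bpifa1, a secreted airway protein, rose by 0.85 with adjusted p = 0.0404 and lost its call in 11 of the 36 fits that left out 1 array each.

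The falls in A/J with the same direction in all weeks were smaller. Aox3, an aldehyde oxidase, fell by 0.46 (adjusted p = 1.28e-05), and Tff2, a trefoil peptide of mucous epithelia, fell by 0.45 (adjusted p = 0.000863). Chad, a cartilage matrix protein, fell by 0.53, the olfactory receptor gene Olfr68 by 0.66, the fatty acid hydroxylase gene Cyp4a12b by 0.61, the microRNA gene Mir181b-1 by 0.54, and H2-Ob, an MHC class II chaperone gene, by 0.43. The late cornified envelope genes Lce1e, Lce1a1 and Lce1j fell by 0.93, 0.72 and 0.46, and lost their calls in 32, 4 and 27 of the 36 fits that left out 1 array each. These 3 skin genes moved with the untreated A/J arrays of week 6, in which the cornified skin gene Lor reached 12.74 and 13.59. Outside these arrays and 1 untreated A/J array of week 0, where Lor was 13.65, its highest level was 7.40.

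Of 26 measured p53 target and DNA damage response genes, 14 rose and 0 fell in A/J, and adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 5.76e-09). The call held with an estimated correlation (adjusted p = 0.042). Psrc1 (10495316), a spindle protein gene induced by p53, rose by 0.89 ± 0.07, from 7.93 ± 0.18 to 8.82 ± 0.29 (SD, n = 8 each, adjusted p = 7.56e-09). Phlda3, which restrains AKT, rose by 0.52 ± 0.04, and Ccng1 (10385271), the cyclin G1 gene, rose by 0.43 ± 0.04 (adjusted p = 2.54e-07). Eda2r, a death receptor gene, rose by 0.51. Other rises were those of the stress sensor Sesn2 by 0.54, the RNA-binding gene Zmat3 by 0.46, Ddit4l, an mTOR inhibitor gene, by 0.46, Trp53inp1 by 0.29 and Mdm2, the ubiquitin ligase gene of p53, by 0.19. The death receptor gene Fas, the apoptosis gene Bbc3 and the antiproliferative gene Btg2 did not pass, with changes of -0.06, 0.01 and -0.16.

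**Figure D1:**
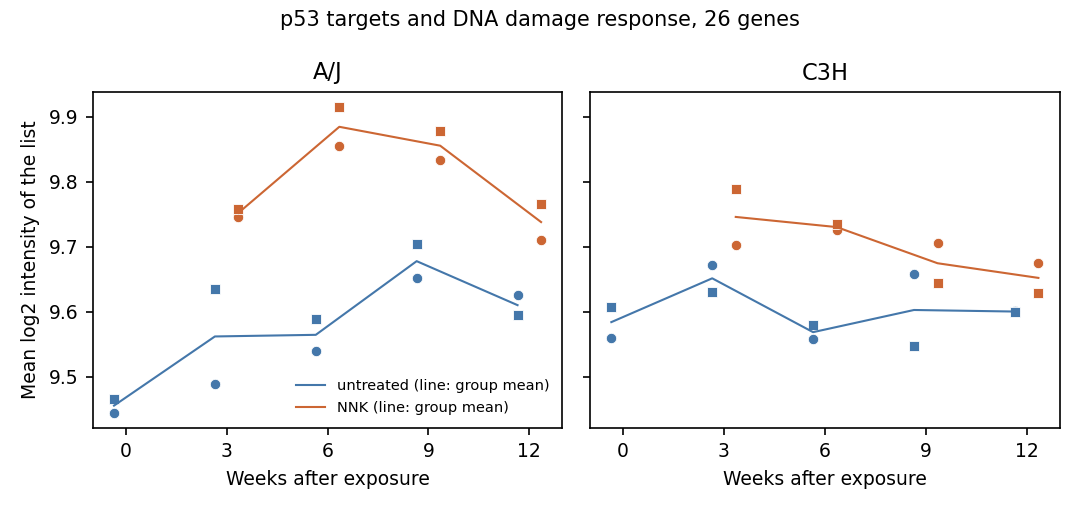
Mean log2 level of the 26 measured p53 target and DNA damage response genes by week in A/J and C3H lungs, untreated in blue and NNK-treated in orange, with circles for replicate 1, squares for replicate 2 and lines through group means. The NNK arrays lie above the untreated mean of their week in 8 of 8 arrays in each strain.

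**Figure D2:**
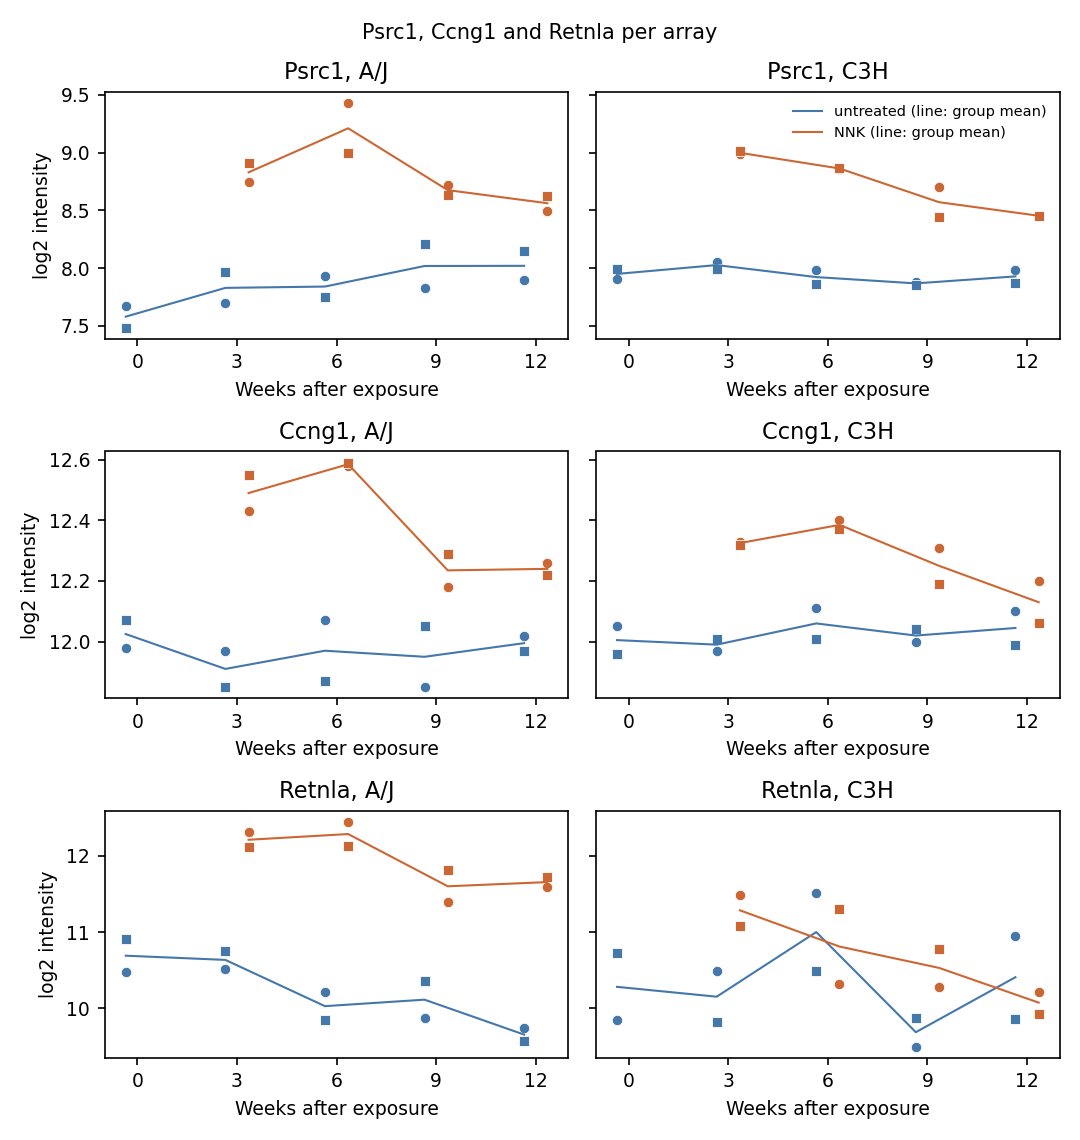
Log2 levels of Psrc1, Ccng1 and Retnla by week in both strains, untreated in blue and NNK-treated in orange, with circles for replicate 1, squares for replicate 2 and lines through group means. Retnla rose by 1.83 in A/J, and its C3H change of 0.36 did not pass.

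Epithelial lists rose as well. Of 29 genes of ciliated cells 19 rose, and 22 adjusted over the list alone (camera adjusted p = 3.43e-12; adjusted p = 0.286 with an estimated correlation). They included the cadherin-related gene Cdhr4 by 0.50, the ciliary genes Dynlrb2 by 0.39 and Lrrc23 by 0.38, and Foxj1, the master regulator of motile cilia, by 0.32. Of 20 alveolar type 2 genes all 20 were higher and 9 rose, and 13 adjusted over the list alone (camera adjusted p = 4.71e-07; adjusted p = 0.286 with an estimated correlation). Scd1, a fatty acid desaturase gene, rose by 0.28, Sftpd, a surfactant protein gene, by 0.26, Lamp3 of lamellar bodies by 0.22 and the chemokine gene Cxcl15 by 0.16. Of 15 cholesterol synthesis genes 12 rose, and 14 adjusted over the list alone (camera adjusted p = 1.81e-10; adjusted p = 0.243 with an estimated correlation), among them Idi1 by 0.37, Sqle by 0.35, Cyp51 by 0.29 and Sc5d by 0.21, which encode enzymes of the pathway. The list of club cells did not pass (camera adjusted p = 0.704). Of its genes the uroplakin gene Upk3a rose by 0.37 and the potassium channel gene Kcnk1 by 0.20, while the paraoxonase gene Pon1 fell by 0.42 and the cholecystokinin receptor gene Cckar fell by 0.22.

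All 32 measured proliferation genes were higher with NNK in A/J and 6 rose, with 24 adjusted over the list alone (camera adjusted p = 9.94e-08; adjusted p = 0.792 with an estimated correlation). The mitotic kinase gene Cdk1 rose by 0.65, the nucleotide reductase gene Rrm2 by 0.48, the topoisomerase gene Top2a by 0.47 and the replication licensing gene Mcm4 by 0.18. The list mean was 9.47 in NNK array 1 of week 6, 8.55 in array 2 and between 8.48 and 8.99 in the other A/J NNK arrays, and Top2a lost its call in 11 of the 36 fits that left out 1 array. The fry test did not call the list (adjusted p = 0.0614). Of 24 DNA repair genes 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.792 with an estimated correlation). These were the recombination gene Brca2 by 0.37, the checkpoint kinase gene Chek2 by 0.33 and the ligase gene Lig1 by 0.21. Of 21 NRF2 and oxidative stress genes 8 rose, also 8 adjusted over the list alone (camera adjusted p = 7.37e-05; adjusted p = 0.243 with an estimated correlation). They included the glutathione peroxidase gene Gpx2 by 0.47, the quinone reductase gene Nqo1 by 0.46, the metallothionein gene Mt1 by 0.37 and the glutathione synthesis gene Gclc by 0.25. The list of the aryl hydrocarbon receptor (AhR) battery did not pass (camera adjusted p = 0.43), and Nqo1 was its 1 member that rose.

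Among immune lists, all 24 interferon response genes were higher in A/J with NNK and 8 rose, with 13 adjusted over the list alone (camera adjusted p = 7.75e-07; adjusted p = 0.305 with an estimated correlation). The antiviral gene Oas2 rose by 0.51, the regulator Irf7 by 0.46, the nucleic acid sensor Zbp1 by 0.38 and Usp18 by 0.25. Of 17 neutrophil genes 5 rose, and 6 adjusted over the list alone (camera adjusted p = 0.000831; adjusted p = 0.792 with an estimated correlation), with Ltf, the histidine decarboxylase gene Hdc by 0.56, the lipocalin gene Lcn2 by 0.55 and the collagenase gene Mmp8 by 0.45. NNK array 1 of week 6 stood apart here too, with the neutrophil gene S100a8 at 9.77 against 7.90 in array 2 and the interferon response gene Rsad2 at 10.65 against 8.96. The neutrophil and DNA repair lists lost their calls without week 6 and 1 untreated week 0 array (adjusted p = 0.666 and 0.429). Of 21 genes of B and plasma cells 20 were lower, with a median of -0.17, and 0 fell, also 0 adjusted over the list alone (camera adjusted p = 0.000103; adjusted p = 0.792 with an estimated correlation). With fry the B and plasma cell list did not pass (adjusted p = 0.252). The B cell receptor regulator Cd22, with -0.23, did not pass in limma (adjusted p = 0.0688). The lists of T and NK cells (camera adjusted p = 0.742) and alveolar macrophages (camera adjusted p = 0.4) did not pass. Zap70, a T cell receptor kinase gene, rose by 0.12 and lost its call in 29 of the 36 fits that left out 1 array. In the macrophage list the chitinase-like gene Chil3 rose by 0.48 and the cathepsin gene Ctsk by 0.31, while the keratin gene Krt79 fell by 0.16 and the fatty acid binding gene Fabp1 fell by 0.28. Of 23 endothelial genes 6 fell, and 8 adjusted over the list alone (camera adjusted p = 7.37e-05; adjusted p = 0.305 with an estimated correlation). The apelin receptor gene Aplnr fell by 0.28, the endothelin receptor gene Ednrb by 0.17, and the receptor kinase genes Tek and Tie1 both by 0.16.

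In C3H lungs NNK raised 2 of the 26 p53 target genes, and the proliferation genes lay higher together without any passing by itself. Both lists were called by camera at the preset correlation only (adjusted p = 0.0565 and 0.342 with an estimated correlation). Over weeks 3 to 12, 12 genes changed, 6 upward and 6 downward, all 12 the same way in all 4 weeks. With each array left out in turn the count ran from 4 to 30, and Psrc1, Dglucy, Ccng1 and Cracr2a passed in every such fit. Psrc1 rose by 0.79 ± 0.07, from 7.94 ± 0.08 to 8.72 ± 0.24 (SD, n = 8 each, adjusted p = 3.9e-07). Dglucy (10397763), a glutamate cyclase gene, rose by 0.34 (adjusted p = 7.89e-06), and Ccng1 by 0.24 (adjusted p = 0.0097). The other rises were the uroplakin gene Upk1a by 0.34, the mucosal chemokine gene Cxcl17 by 0.31 and the cyclin gene Ccna1 by 0.25. Cracr2a, a calcium channel regulator gene, fell by 0.23 (adjusted p = 0.00483). The proton pump gene Atp6v1b1 fell by 0.32, the acyl-CoA oxidase gene Acoxl by 0.27, Tbc1d30 of the Rab regulators by 0.24, the complement C5 gene Hc by 0.22 and the lymphatic vessel gene Mmrn1 by 0.20. All 6 rises were among the rises in A/J, where independent calls would give 0.447. Of the 6 falls 1 was among the falls in A/J, where independent calls would give 0.156. Both sets of calls share 1 variance estimate per gene, so they are not independent and these values may be too low. Across all genes tested the changes of both strains had r = 0.104 and rho = -0.0113, and genes are not independent replicates.

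All 32 proliferation genes were higher with NNK in C3H, with a median of 0.27, and 0 rose in limma, though 18 did adjusted over the list alone (camera adjusted p = 9.77e-23; adjusted p = 0.342 with an estimated correlation). The fry test did not call this list (adjusted p = 0.359). The mitotic genes Ube2c, Ccna2, Aurkb and Ccnb2 had changes of 0.51, 0.50, 0.46 and 0.42. Among all 14953 genes, 936 had an unadjusted p under 0.05. Of the p53 list 2 genes rose, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 3.29e-08; adjusted p = 0.0565 with an estimated correlation). The other 10 lists called at the preset correlation had adjusted p between 1.38e-05 and 0.0373, and between 0.342 and 0.87 with an estimated correlation. Of these, neutrophils, extracellular matrix, mesothelium, NRF2 and interferon response were higher with NNK. Alveolar type 2 cells, alveolar macrophages, B and plasma cells, endothelial cells and lymphatic endothelial cells were lower. With fry the 10 lists had adjusted p between 0.149 and 0.868. Without week 6 and 1 untreated A/J array of week 0 the interferon and B cell calls ended (camera adjusted p = 0.0694 and 0.607). The matrix list mean at week 3 was 11.33 and 11.04 with NNK and 10.89 and 10.94 untreated. At week 6 it was 10.96 and 10.95 with NNK and 10.94 and 10.97 untreated. NNK array 1 of week 3, with 11.33, also held Saa3 at 13.33. The lists of club cells, AhR battery and T and NK cells did not pass (camera adjusted p = 0.281, 0.302 and 0.153).

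By week, Psrc1 rose in A/J at weeks 3, 6 and 9 by 1.0, 1.37 and 0.66, and its week 12 change of 0.54 did not pass (adjusted p = 0.13). In C3H it rose at weeks 3 and 6 by 0.97 and 0.94, and the changes of 0.70 and 0.53 at weeks 9 and 12 did not pass (adjusted p = 0.277 and 1). In A/J at week 3, 53 genes changed (43 upward), led by Psrc1, Plcd4 at 0.91 and Upk3a at 0.89. Angptl4, a lipase inhibitor gene, fell by 1.59, the vasodilator gene Adm by 1.15 and the natriuretic peptide receptor gene Npr3 by 0.95. With 1 array left out in turn this count ran from 19 to 581. At week 6, 1087 genes changed, 652 upward and 435 downward. On the deposited scale without normalization 546 rose and 834 fell, 39.6% upward in place of 60.0%. Without untreated A/J array 1 of week 6 the count was 81, the lowest with 1 array left out, and the highest was 1534. The acute-phase gene Saa3 rose by 3.16, an immunoglobulin kappa variable segment (probe set 10538882) by 2.35, and Retnla by 2.25. The skin genes Lor, Krt1 and Hrnr fell, with changes of -6.29, -5.36 and -5.20, and Krt1 stood at 14.37 and 14.77 in the 2 untreated A/J arrays of week 6, against at most 9.72 in the arrays other than these and 1 untreated A/J array of week 0. At week 9, 231 genes changed (175 upward). Retnla rose by 1.49, Ltf by 1.37 and Lrg1 by 1.37, while the albumin gene Alb fell by 2.55 and the olfactory receptor genes Olfr68 and Olfr1362 fell, with changes of -1.5 and -0.62. At week 12, 11 genes rose, led by Retnla at 2.0, the uncharacterized BC023105 at 1.55 and the interferon-induced chemokine gene Cxcl9 at 1.49. With 1 array left out in turn the counts of weeks 9 and 12 ran from 0 to 1210 and from 0 to 23, and 0 of the genes named for these weeks passed limma in every such fit.

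In C3H at week 3, 14 genes changed, 4 upward and 10 downward. Saa3 rose by 4.99 and the lubricin gene Prg4 by 4.40. Both were also high in 1 untreated A/J array of week 3, at 12.32 and 11.30. Fabp1 fell by 0.88, the homeobox gene Meox1 by 0.56 and the peptidase gene Xpnpep2 by 0.53. With 1 array left out in turn the count ran from 0 to 425, and 0 of the genes named for this week passed limma in every such fit. At week 6 Psrc1 and Dglucy rose, the latter by 0.54. At weeks 9 and 12 limma called 0 genes, with 281 and 182 at an unadjusted p under 0.05. Both were under a share of 0.05 of the 14953 genes, which chance alone would give. The fit used 1 spread for both strains, and the median residual SD was 0.106 in A/J and 0.0798 in C3H. P-values in C3H may therefore be too large, and 0 calls do not show that NNK had no effect at these weeks. The NNK change varied over the weeks for 33 genes in A/J, led by the skin genes Krt1, Krt10, Hrnr and Ivl, and for 0 genes in C3H by the moderated F test of limma. With 1 array left out in turn these counts ran from 11 to 553 and from 0 to 52. In the simulation this test recovered 50% of the changes of 0.5 in A/J and called 41 unchanged genes, more than the threshold of 0.05 allows. Dglucy (adjusted p = 0.0142) and Upk3a (adjusted p = 0.0207) were among the 33, and Dglucy rose in A/J by 0.68, 0.92 and 0.52 at weeks 3, 6 and 9, with 0.24 at week 12.

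The NNK change was higher in A/J than in C3H for Retnla and for 5 genes of ciliated cells, 7 of cholesterol synthesis, 4 of alveolar type 2 cells and 4 of the p53 list. These lists lost their calls in camera without the preset correlation (adjusted p = 0.307, 0.288, 0.288 and 0.307 with an estimated correlation). In all 169 genes differed, 150 with the higher change in A/J and 19 with the higher change in C3H. Without week 6 and 1 untreated week 0 array 5 genes differed, and with each array left out in turn the count ran from 49 to 1080. Of the 39 called genes named for this comparison, 12 passed in all 36 of these fits and 27 did not. Retnla had a difference of 1.47 ± 0.26 (SE, adjusted p = 0.00946), with 1.83 in A/J and 0.36 in C3H (adjusted p = 0.815), and passed in every such fit. Alkal1, which encodes a ligand of the receptor ALK, had a difference of 0.67 (adjusted p = 0.00431). Clca3b had 1.06, A2ml1 0.92, Mfsd2a 0.78, Ccl8 0.62 and Lcn2 0.61. The platelet chemokine gene Ppbp had 0.81, from changes of 0.23 in A/J and -0.57 in C3H that did not pass in either strain. Snora69, a small nucleolar RNA gene, had 0.71 and the neuronal gene Nrgn 0.62. Differences below 0 were led by Mir185 at -0.37, the collagen gene Col6a4 at -0.37 and the odorant receptor-like gene Taar7b at -0.37. For Psrc1 the difference of 0.11 did not pass (adjusted p = 0.562), nor did that of 0.19 for Ccng1 (adjusted p = 0.0876).

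Of the lists, 5 of 29 ciliated genes differed, and 20 adjusted over the list alone (camera adjusted p = 5.52e-13; adjusted p = 0.307 with an estimated correlation), among them Pifo with 0.57, Dynlrb2 with 0.47, Lrrc23 with 0.44 and the dynein gene Dnaic1 with 0.27. Of 15 cholesterol synthesis genes 7 differed, and 12 adjusted over the list alone (camera adjusted p = 2.32e-11; adjusted p = 0.288 with an estimated correlation), with Idi1 at 0.43, Cyp51 at 0.35, Msmo1 at 0.34 and Sc5d at 0.30. All 20 alveolar type 2 genes were higher in A/J in this contrast and 4 differed, with 13 adjusted over the list alone (camera adjusted p = 5.24e-10; adjusted p = 0.288 with an estimated correlation). These 4 were Sftpd with 0.34, Hc with 0.30, Lamp3 with 0.29 and the chitinase-like gene Chil1 with 0.25. Of the p53 list 4 genes differed, and 6 adjusted over the list alone (camera adjusted p = 0.00135; adjusted p = 0.307 with an estimated correlation): Sesn2 with 0.41, Phlda3 with 0.39, Eda2r with 0.32 and the translesion polymerase gene Polk with 0.22. The interferon list passed (camera adjusted p = 0.00485; adjusted p = 0.938 with an estimated correlation) with Oas2 at 0.44, and 1 gene adjusted over the list alone. The stress response list passed (0.0161; adjusted p = 0.907 with an estimated correlation), as did lymphatic endothelial cells (0.0324; adjusted p = 0.45 with an estimated correlation), each with 1 gene past, 2 adjusted over the list alone. The DNA repair list had camera adjusted p = 0.0492 and 0 genes past by limma, and adjusted p = 0.996 with an estimated correlation. Its call also ended with fry (adjusted p = 0.162), and in camera on the deposited scale (0.0999) and with the array number as a block (0.0533). The same held with the array median as a covariate (0.0797) and without week 6 and 1 untreated A/J array of week 0 (0.296). Mesothelium was lower in A/J with a median of -0.30 (0.0161, and adjusted p = 0.996 with an estimated correlation). With fry the calls of mesothelium and of the interferon list ended (adjusted p = 0.646 and 0.122). That of the stress response list ended in camera without week 6 and 1 untreated A/J array of week 0 (adjusted p = 0.0547). The proliferation list did not differ between the strains past the threshold (camera adjusted p = 0.838).

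Untreated A/J and C3H lungs differed most in single genes such as those of a kallikrein, a bone marrow stromal antigen and dysferlin, and A/J had higher levels of mucous, ciliated and B cell genes and lower levels of alveolar macrophage and clock genes. Each of these list calls was lost in camera without the preset correlation (adjusted p = 0.954 with an estimated correlation), and with weeks 6 to 12 only those of mucous, ciliated, B cell and clock genes ended (adjusted p = 0.0543, 0.0778, 0.22 and 0.649). Their medians were then 0.246, 0.0898, 0.114 and -0.0439, in place of 0.312, 0.14, 0.189 and -0.434. Of 14953 genes 8394 differed, 2962 higher and 5432 lower in A/J, 6342 of them the same way in all 5 weeks and 489 by at least 1.5-fold. Sequence differences between the strains under a probe can give such differences. Klk1b22, a kallikrein gene, had 5.36 ± 0.47 in A/J and 10.57 ± 0.23 in C3H (SD, n = 10 each), a difference of -5.21 (adjusted p = 1.39e-18). Its A/J level lay under the 10th percentile of deposited intensity, 49.6 to 84.4 over the arrays, so the size of this difference was set by the background and the pseudocount. Bst1, a bone marrow stromal antigen gene, was lower in A/J by -4.06, the immunoglobulin segment Igkv4-91 by -3.17 and Alkal1 by -2.78. Dysf, the dysferlin gene, in which A/J mice are known to be deficient, was lower by -2.82. Abca17, Zfp605, Nme7, the nuclease gene Dnase1l3 and Sfmbt2 had differences from -2.09 to -1.74. The neuronal pentraxin gene Nptx1 was higher in A/J by 2.90, the small nucleolar RNA genes Snord118 and Snora33 by 2.83 and 2.16, the atrial peptide gene Nppa by 2.56, the MHC gene H2-T10 by 2.54 and the airway protein gene Bpifb1 by 2.0. Zfp640 and Olfr1184, at 2.32 and 2.05, had SDs of 2.47 and 2.06 over the A/J arrays. The mean of 44 small nucleolar RNA genes was 9.82 ± 0.21 in A/J and 9.24 ± 0.10 in C3H over untreated and NNK arrays together (SD, n = 18 each).

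The calls of the cholesterol synthesis and cardiac muscle lists were lost in the same way (adjusted p = 0.954 with an estimated correlation), and that of cholesterol synthesis ended with weeks 6 to 12 only (adjusted p = 0.127), with a median of 0.0817 in place of 0.131. Of 20 alveolar macrophage genes 3 were higher and 15 lower in A/J (camera adjusted p = 0.00167), with the glycoprotein gene Gpnmb at -0.98, the proton pump gene Atp6v0d2 at -0.79, the nuclear receptor gene Pparg at -0.54 and Plet1 at -0.45. Of 14 mucous genes 8 were higher (camera adjusted p = 0.00129), among them Bpifb1, Ltf by 1.24, the mucin gene Muc5b by 0.95 and Tff2 by 0.43. Of 29 ciliated genes 16 were higher and 1 lower (0.000246), of 21 B and plasma cell genes 9 were higher (0.00469), and of 15 cholesterol synthesis genes 9 were higher and 2 lower (0.0178). In these groups Dynlrb2 was higher by 0.57, the antibody gene Igha by 1.09, the B cell regulator Pax5 by 0.67, and the sterol genes Stard4 and Insig1 by 0.67 and 0.55, while the ciliary gene Sntn was lower by -0.66. Of 16 clock genes 1 was higher and 12 lower (0.00409), with the transcription factor genes Hlf at -0.98 and Dbp at -0.84. Of 20 cardiac muscle genes 10 were higher and 3 lower (0.0292), with the atrial myosin gene Myl7 at 1.12. This call ended with fry (adjusted p = 0.0894), and without week 6 and the untreated A/J week 0 array in which the muscle gene Acta1 stood at 14.31 (adjusted p = 0.197), where the median was 0.14 in place of 0.233. Adjusted over the list alone the higher and lower counts were the same for alveolar macrophages, mucous, ciliated and cholesterol genes, 7 higher for B and plasma cells, 12 and 3 for cardiac muscle, and 2 and 12 for clock genes.

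Over 12 weeks in untreated lungs, genes of the extracellular matrix fell in both strains, and clock genes moved in A/J. Of other lists, 10 genes of B and plasma cells, 9 of the glucocorticoid response and 6 of MHC rose. The calls of these 3 lists were lost in camera without the preset correlation (adjusted p = 0.779, 0.603 and 0.779 with an estimated correlation), and the median of the glucocorticoid list was -0.28 over weeks 6 to 12 alone in place of 0.30. In all 2862 genes had a trend, 2004 upward and 858 downward, 86 of them by at least 1.5-fold. On the deposited scale without normalization 675 rose and 1145 fell, 37.1% upward in place of 70.0%. With weeks 6 to 12 only, 5 genes had a trend. Of 29 extracellular matrix genes 20 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 9.11e-18), and the call held with an estimated correlation (adjusted p = 0.0171). Col3a1 (10346015), the collagen III gene, fell by 0.81 ± 0.09 (SE, adjusted p = 6.28e-06), from 10.94 ± 0.05 at week 0 to 10.19 ± 0.04 at week 12 (SD, n = 4 each), with -0.86 in A/J and -0.75 in C3H. The collagen crosslinking gene Loxl1 fell by 0.64, the collagen V gene Col5a2 by 0.55 and the gelatinase gene Mmp2 by 0.47. Alone, A/J had 14 falls in this list (camera adjusted p = 7.2e-13) and C3H had 8 (camera adjusted p = 1.46e-16). With an estimated correlation 0 of 42 lists passed camera in A/J alone, so the call of this list was lost there.

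**Figure D3:**
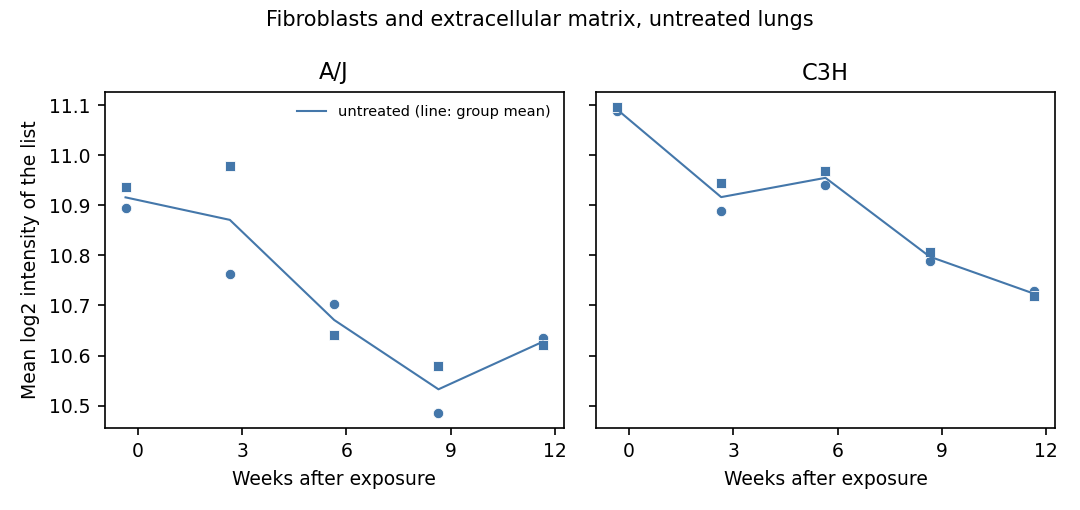
Mean log2 level of 29 extracellular matrix genes in untreated lungs by week, in A/J and C3H, with circles for replicate 1, squares for replicate 2 and lines through group means. Of these genes 20 fell over 12 weeks.

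Of 16 clock genes 11 rose and 2 fell, and adjusted over the list alone 12 rose and 2 fell (camera adjusted p = 2.52e-08; adjusted p = 0.243 with an estimated correlation). The trend of this list differed between the strains, with 12 genes higher and 2 lower in A/J, and 13 and 2 adjusted over the list alone (camera adjusted p = 3.07e-16), also with an estimated correlation (adjusted p = 0.0366). In C3H alone 0 clock genes passed in limma (camera adjusted p = 0.408), where 1813 of all 14953 genes had a trend at an unadjusted p under 0.05. Per1 (10377439), a core repressor of the clock, rose by 1.18 ± 0.12 (SE, adjusted p = 2.76e-06), with 2.12 in A/J and 0.24 in C3H, and this difference passed (adjusted p = 0.000241). The movement in A/J was not steady. A clock score, the mean of Per and Dbp phase genes minus that of opposite-phase genes, averaged 1.33, 0.2, 2.33, 2.03 and 2.48 in untreated A/J at weeks 0, 3, 6, 9 and 12, and between 2.27 and 2.55 in untreated C3H. In the linear contrast Per2 rose by 1.01, the repressor gene Bhlhe41 by 1.03, the ubiquitin protease gene Usp2 by 0.96 and Ciart by 0.94. In all 197 genes had trends that differed between the strains, 164 higher and 33 lower in A/J. A/J alone had 3410 genes with a trend and C3H alone 129.

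Other rises over the weeks were those of Alb by 1.74 ± 0.30, the antibody joining chain gene Jchain by 1.64, the hormone-induced transcription factor gene Zbtb16 by 1.34, the amino acid transporter gene Slc6a20a by 0.99 and Snord118 by 0.98. Of 21 B and plasma cell genes 10 rose, and 13 adjusted over the list alone (camera adjusted p = 4.53e-05; adjusted p = 0.779 with an estimated correlation), with the antibody gene Ighm by 0.66. Of 15 glucocorticoid response genes 9 rose, also 9 adjusted over the list alone (0.000446; adjusted p = 0.603 with an estimated correlation), among them Tsc22d3 by 0.87. Of 14 MHC genes 6 rose, and 10 adjusted over the list alone (0.0015; adjusted p = 0.779 with an estimated correlation). Of 17 NNK activation and detoxification genes 7 rose, and 8 adjusted over the list alone (0.0298; adjusted p = 0.779 with an estimated correlation), with the monooxygenase genes Fmo2 by 0.33 and Cyp2b10 by 0.27, the epoxide hydrolase gene Ephx1 by 0.31 and the carbonyl reductase gene Cbr3 by 0.26. This call ended without the dim filter (adjusted p = 0.164) and with weeks 6 to 12 only (adjusted p = 0.819), where the median was 0.0325 in place of 0.168.

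The goblet cell gene Clca1 fell by 1.82 and the antimicrobial lectin gene Reg3g by 1.09. Of 14 mucous genes 5 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.00023; adjusted p = 0.587 with an estimated correlation), with Agr2, a mucin-folding gene, by 0.77. Of 20 alveolar type 2 genes 4 fell (0.000892; adjusted p = 0.779 with an estimated correlation), of 16 smooth muscle genes 3 fell (0.0015; adjusted p = 0.779 with an estimated correlation) and of 17 neutrophil genes 1 fell (0.0188; adjusted p = 0.888 with an estimated correlation). Adjusted over the list alone these counts were 5, 7 and 1. These 3 calls ended with fry (adjusted p = 0.0734, 0.152 and 0.407) and with weeks 6 to 12 only (adjusted p = 0.314, 0.709 and 0.709), where the medians of smooth muscle and neutrophil genes were -0.0268 and -0.0122 in place of -0.128 and -0.195. That of neutrophils also ended on the deposited scale (adjusted p = 0.0516) and without the filter on dim genes (adjusted p = 0.158). Of 5 AhR battery genes 1 fell, also adjusted over the list alone (0.0336; adjusted p = 0.448 with an estimated correlation), the cytochrome gene Cyp1a1 by 0.94. This list call ended on the deposited scale (adjusted p = 0.0602), with the array median as a covariate (0.0559), without week 6 and the A/J week 0 array with muscle markers (0.0818) and with weeks 6 to 12 only (0.715). Without the filter on dim genes its median was -0.0336 in place of -0.133 (adjusted p = 0.286). The largest falls were those of Olfr1184, at -2.40, and Zfp640, at -2.35, followed by Vmn2r-ps104, Mir680-2, Krtap19-2, Olfr1138, Olfr346 and Olfr1008, with changes from -1.54 to -1.15. Zfp640 and Olfr1184 had SDs of 2.93 and 2.31 over the 4 arrays of week 0, which hold both strains. Zfp640 then stood at 12.6 and 12.8 in A/J and at 7.7 and 7.5 in C3H. In untreated A/J it stood at 12.4 and 7.3 at week 3 and at 7.6 and 7.6 at week 12. In C3H it stood at 7.4 and 7.3 at week 12, so its fall was that of A/J and differed between arrays of a group.

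**Figure D4:**
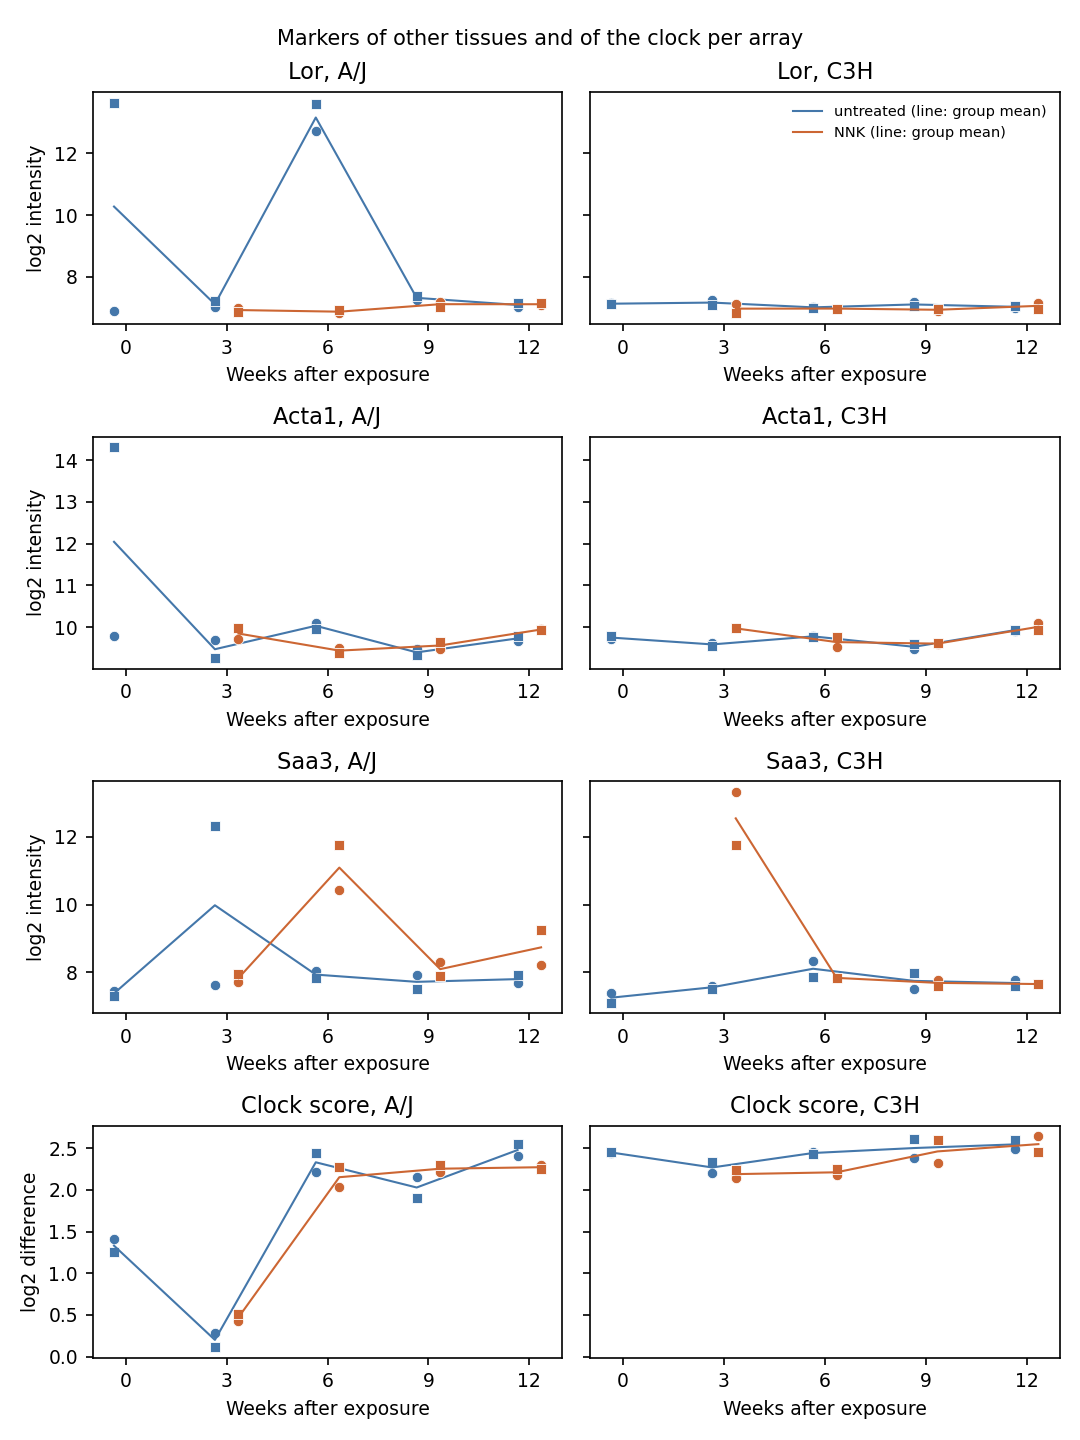
Log2 levels of Lor, Acta1 and Saa3 and a clock score, the mean of clock genes of the Per and Dbp phase minus the mean of genes of the opposite phase, by week in both strains, with circles for replicate 1, squares for replicate 2 and lines through group means. Lor stood at 12.74 and 13.59 in the untreated A/J arrays of week 6, and the muscle gene Acta1 at 14.31 in 1 untreated A/J array of week 0.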

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

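The tests on other splits of the arrays were chosen beforehand, and the tests of array-wide intensity, pooled spread, week 6, skin genes and clock genes were chosen only after the results had been seen. No group had the 4 arrays that a test of a single array far from its group needs, so no such test was run.

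A difference between groups marked the 169 genes whose NNK change differed between A/J and C3H. The named genes with the higher change in A/J were Retnla by 1.465, Clca3b by 1.064, A2ml1 by 0.92, Ppbp by 0.81, Mfsd2a by 0.78, Snora69 by 0.71, Alkal1 by 0.67, Ccl8 by 0.62, Nrgn by 0.62 and Lcn2 by 0.61 on the log2 scale. Those with the higher change in C3H were Mir185 at -0.37, Col6a4 at -0.37, Taar7b at -0.37, Mir125a at -0.31, 5730408K05Rik at -0.30, 1520401A03Rik at -0.289, Mfsd4a at -0.28, Hmx1 at -0.28, Scn8a at -0.26 and Erich4 at -0.25. Of the gene lists, the median difference was 0.278 for cholesterol synthesis, 0.233 for ciliated cells, 0.18 for the interferon response, 0.165 for lymphatic endothelial cells, 0.158 for alveolar type 2 cells, 0.12 for p53 targets, 0.0995 for DNA repair, 0.0976 for the unfolded protein and integrated stress response and -0.299 for mesothelium. With an estimated correlation 0 of these 9 lists passed camera, and the largest list, the ciliated genes, had 20 of 29 members past when adjusted over the list alone. Leaving out week 6 in both strains left 3 genes past the threshold, all 3 among the 169, against 222 without week 3, 34 without week 9 and 17 without week 12. The count fell furthest without week 6, the week of the untreated A/J arrays with high levels of skin genes. That week also had the largest mean NNK change of the p53 list, 0.32 in A/J and 0.162 in C3H. The fall therefore cannot be assigned to the skin genes. Of 100 splits 1, the real one, reached 169, and the highest other gave 10. Other splits can put NNK-treated and untreated arrays under 1 group mean, which widens the spread, so they cannot exclude chance.

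A difference between time points marked the 33 genes whose NNK change varied over the weeks in A/J, which were led by skin genes. A difference between the strains also marked the 197 genes with unequal week trends in untreated lungs and the clock list, whose median trend over 12 weeks was higher in A/J by 0.873.

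A signal in probe sets outside the comparisons came from those with no or several gene symbols. Of 7814 such probe sets above the dim filter, 83 changed with NNK in A/J, 64 of them upward, and 0 in C3H by the same limma fit. They were 15 of 1144 with several symbols and 68 of 6670 with none.

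More genes changed with NNK in A/J (1502) than in C3H (12). In the simulation the same fit called 40 unchanged genes in A/J, more than the threshold of 0.05 allows, and 1 in C3H. Part of the A/J count may therefore be unchanged genes. The array median as a covariate left 1405 genes in A/J and 14 in C3H, each strain's own arrays gave 483 and 41, and leaving out week 6 and 1 untreated week 0 A/J array gave 492 and 2, so array-wide intensity, the pooled spread and carried-over skin are each argued against as the whole cause, though the A/J count fell in the latter pair. Without week 3, 6, 9 or 12 in turn, A/J gave 2170, 469, 601 and 1089 genes. The count also fell without week 9, so its fall without week 6 cannot be assigned to skin. In both strains 1 of 100 splits, the real one, reached the count. Other splits can put NNK-treated and untreated arrays under 1 group mean, which widens the spread and lowers their counts. The 2 arrays of a group may also not be separate animals, so the splits cannot exclude chance. The highest other split in A/J gave 1425 genes, against 4 in C3H. That A/J split had 10 of 16 real labels and the largest difference in array medians (-0.0848, against -0.0273 for the real one), and with the covariate it gave 3 genes and the highest other split 700, which points to a structure of array-wide intensity within A/J. A stronger response of the susceptible strain stays open as a biological hypothesis, as do a few doubtful arrays acting together, which were not tested jointly.

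Skin genes were lower with NNK in A/J: of 20 measured genes of the cornified epidermis 11 passed, with a median of -0.412 over the 4 weeks. At week 6 the median was -1.37 (SD over members 1.76), and over weeks 3, 9 and 12 it was -0.0523 (SD over members 0.132). The pattern is consistent with skin carried over into the untreated A/J arrays of week 6, which held Krt1 at 14.37 and 14.77. The NNK arrays of week 6 held Krt1 at 9.22 and 9.20, and their list median differed from that of untreated A/J weeks 3, 9 and 12 by -0.114 (SD over members 0.128), which argues against a loss with NNK. The same untreated arrays enter every A/J contrast of week 6.

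Clock genes had a linear trend in untreated A/J lungs, but their score (Per and Dbp phase genes minus opposite-phase genes) averaged 1.33, 0.2, 2.33, 2.03 and 2.48 at weeks 0, 3, 6, 9 and 12, with a net change of 1.15. In untreated C3H the score changed by 0.0978, which argues against a gradual change with age in both strains, and the change of -1.13 from week 0 to week 3 in A/J, against a largest gap within a group of 0.286, argues against a steady rise with age in A/J alone. The NNK-treated A/J arrays of week 3 were low like the untreated ones of that week, which had 0.289 and 0.111, with a highest score of 0.513, while the lowest A/J array of weeks 6 to 12 had 1.91. This is consistent with another time of day of collection for A/J at weeks 0 and 3, a candidate explanation found from these data, as collection times were not given in the sources used here. A change with age in A/J that is not steady stays open.

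For the strain difference and the week trend too, 1 of 100 splits, the real one, reached the count. The highest other split gave 4947 genes against 8394 for the strains and 1541 genes against 2862 for the trend. Other splits can put arrays of both strains, or of different weeks, under 1 group mean, which widens the spread. They therefore cannot exclude chance here either.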

How the results depend on the processing

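The alternatives with the array median as a covariate, 1 variance per strain, without week 6 and 1 untreated A/J array of week 0, and weeks 6 to 12 only were chosen after seeing the data, and the others before. Counts below are of genes past the threshold, given where they moved by more than 1.5 times. The cause was not tested unless fewer arrays or other genes tested give it by construction.

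On the deposited scale A/J week 12 gave 17 genes in place of 11 and the trend 1820 in place of 2862, while A/J week 6 (1380 in place of 1087) turned from mostly higher to mostly lower. No named gene reversed on that scale. Without the dim filter the interaction gave 97 and the trend 4474. With the 50th percentile as filter A/J week 6 gave 432, C3H week 6 gave 1, the trend 1731 and the A/J week dependence 7. Trended robust variances gave 20 for the A/J week dependence. Array weights gave 675 in A/J, 7, 563, 4 and 18 at its weeks 3, 6, 9 and 12, 31 in C3H, 127 and 1 at its weeks 6 and 9, 111 for the interaction, and 5 and 1 for the week dependence in A/J and C3H. Each strain's own arrays gave 483 in A/J, 14, 170, 10 and 3 by week and 5 for its week dependence, and 41 in C3H, 25, 4 and 1 at its weeks 3, 6 and 9 and 1 for its week dependence. The additive model gave 3 in C3H. Other counts under these alternatives stayed within 1.5 times.

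The array numbers did not pair the arrays: correlations of the arrays of 1 number between groups ran from -0.25 to 0.27 in A/J and -0.31 to 0.41 in C3H. With the array number as a block the A/J week dependence gave 20 genes, and A/J 1501, C3H 11, the interaction 193, the strains 8398 and the trend 2887.

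The array median as a covariate gave 258, 225 and 476 at A/J weeks 3, 6 and 9 and 17 for its week dependence. One variance per strain gave 735 in A/J, 24, 299, 4 and 2 by week and 4 for its week dependence, and 30 in C3H, 244 and 1 at its weeks 3 and 9 and 3 for its week dependence. Without week 6 and the A/J array, A/J gave 492 genes (451 shared with the 1502), C3H 2, the interaction 5 and the trend 1513. With weeks 6 to 12 only the trend gave 5.

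With each array left out in turn, a lone array was assumed to vary like the other groups. The counts ran from 900 to 2963 in A/J, 4 to 30 in C3H, 49 to 1080 for the interaction, 7894 to 8664 for the strains and 1669 to 3707 for the trend. By week they ran from 19 to 581, 81 to 1534, 0 to 1210 and 0 to 23 in A/J and from 0 to 425, 0 to 4, 0 to 1 and 0 to 0 in C3H, and for the week dependence from 11 to 553 in A/J and 0 to 52 in C3H.

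In the following, U and N mark untreated and NNK arrays with their week and the array number. A/J gave 954 without A/J U3-1, 2963 without U3-2, 900 without U6-1 and 927 without N9-2. C3H gave 30 without A/J N6-1 or N6-2, 25 without C3H N3-2, 4 without C3H U3-1, N3-1 or N6-2, 5 without U3-2, U6-1, U9-2, N6-1, N9-1, N12-1 or N12-2 and 7 without U9-1, U12-1, U12-2 or N9-2. The interaction gave, without A/J arrays, 69 (U3-1), 1080 (U3-2), 88 (U6-1), 342 (U12-1), 58 (U12-2), 83 (N3-2), 52 (N9-2), 97 (N12-1) and 88 (N12-2), and without C3H arrays 54 (U3-1), 49 (U6-1), 101 (U6-2), 62 (U9-1), 50 (U12-1), 78 (U12-2), 59 (N3-1), 332 (N3-2), 94 (N6-1), 51 (N6-2), 62 (N9-2) and 57 (N12-1). The trend gave 1776 without A/J U12-2, 1712 without C3H U0-1 and 1669 without C3H U12-2. A/J week 3 gave 182 (U3-1), 581 (U3-2), 22 (N3-1) and 19 (N3-2), week 6 gave 81 (U6-1) and 323 (N6-1), week 9 gave 396 (U3-1 or U3-2), 1210 (U9-1), 9 (U9-2), 75 (N9-1) and 0 (N9-2), and week 12 gave 0 (U12-2 or N12-1), 22 (N6-1 or N6-2) and 23 (N12-2). C3H week 3 gave 32 without A/J U3-1 or U3-2, 0 without C3H U3-1, U3-2 or N3-1 and 425 without N3-2, week 6 gave 0 (U6-2), 4 (N6-1) and 1 (N6-2), and week 9 gave 1 (N9-1). The A/J week dependence gave, without A/J arrays, 52 (U0-1 or U0-2), 398 (U3-1), 19 (U6-1 or N9-2), 553 (U9-1), 20 (U9-2), 11 (N3-1), 132 (N6-2) and 21 (N12-1), and without C3H arrays 21 (U3-1 or U3-2), 20 (U6-1 or U6-2) and 71 (N3-1 or N3-2). That of C3H gave 1 without A/J U3-1 or U3-2 and 52 without C3H N3-2.

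Of the named genes called, 52 of 69 in A/J, 4 of 12 in C3H, 12 of 39 in the interaction, 46 of 46 in the strains and 39 of 51 in the trend passed in each of these fits. None of their directions reversed where they were recomputed. The deposited scale ended 15 of their calls and added 3, a pseudocount of 1 ended 2, and the array number as a block ended 8 and added 1.

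Of 51 list calls, 2 held with an estimated correlation and 31 with fry. The median of the glucocorticoid list in the trend reversed to -0.276 with weeks 6 to 12 only (adjusted p = 0.00233), from 0.305, and 10 of the 18 lists of the strains and the trend lost their calls there. The deposited scale ended 4 calls, no dim filter 4, the block 1, the covariate 2, 1 variance per strain 0, and leaving out week 6 and the A/J array 8. Signal over background limits dim genes, whose changes the pseudocount of 16 shrinks.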

Other observations

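The list tests of single weeks were chosen beforehand, and the lists given here, the spread of the strains, the principal components and the tests of the p53 list were chosen only after the results had been seen.

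In A/J at week 12 limma called 11 genes, while lists of genes lay higher together with NNK. All 24 interferon response genes were higher, with a median of 0.383, and 14 passed adjusted over the list alone (camera adjusted p = 2.88e-20; adjusted p = 0.054 with an estimated correlation). All 20 alveolar type 2 genes were higher (camera adjusted p = 1.87e-14; adjusted p = 0.0672 with an estimated correlation). All 11 adipose genes were higher, with a median of 0.767 (camera adjusted p = 1.04e-09; adjusted p = 0.194 with an estimated correlation), and the brown fat gene Ucp1 stood at 11.87 and 10.42 in the 2 NNK arrays and at 9.99 and 8.16 in the 2 untreated arrays of that week, against a median of 7.22 over all arrays.

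At week 3 the mesothelium list moved in opposite directions in the strains, with a median of -0.682 in A/J (camera adjusted p = 1.87e-05; adjusted p = 0.465 with an estimated correlation) and 0.899 in C3H (camera adjusted p = 7.53e-08; adjusted p = 0.337 with an estimated correlation). The difference at week 3 was not tested. The arrays with high Saa3 and Prg4, both NNK arrays of C3H and 1 untreated array of A/J, lie on the higher side of each contrast.

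In A/J at week 6 all 17 neutrophil genes were higher with NNK, with a median of 1.09, and 9 rose (camera adjusted p = 1.42e-08; adjusted p = 0.626 with an estimated correlation). NNK array 1 stood apart, with S100a8 at 9.77 against 7.90 in NNK array 2 and 7.27 and 7.56 in the untreated arrays, and with the proliferation gene Mki67 at 10.50 against 9.05 in NNK array 2.

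In A/J the gap between the arrays of a group was wider than in C3H. The median residual SD was 0.106 in A/J and 0.0798 in C3H, a ratio of 1.32. The second principal component held 10.4% of the variance and had r = -0.888 with the array median over the 18 A/J arrays, a description of the arrays without a test.

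The NNK change of the p53 list was tested for a decline with the weeks after exposure. The mean changes at weeks 3, 6, 9 and 12 were 0.19, 0.32, 0.178 and 0.128 in A/J and 0.0944, 0.162, 0.0719 and 0.0518 in C3H. Over 8 NNK arrays of each strain, rho was -0.586 in A/J (exact permutation p = 0.153, adjusted 0.247) and -0.488 in C3H (exact permutation p = 0.247, adjusted 0.247), both two-sided over 2520 orders and 2 relations. Pearson's r was -0.493 (exact permutation p = 0.229, adjusted 0.229) and -0.482 (exact permutation p = 0.218, adjusted 0.229). With 2 arrays farthest from the median week left out, r ran from -0.916 to -0.0754 in A/J and from -0.851 to -0.188 in C3H over 6 choices of tied arrays. A decline was not shown, and the 2 NNK arrays of a week share 1 untreated mean, so they are not fully independent. In both strains 8 of 8 arrays lay above 0.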
